A study of Mus musculus with 8 samples.

How the data were processed

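Transcripts of 5006 mouse genes were counted in formalin-fixed, paraffin-embedded lung sections with the Xenium Prime assay, an in situ imaging method in which probes bound to transcripts are decoded on the tissue and assigned to cells outlined with segmentation stains. The labels give 2 control and 6 AML lung sections (AML, acute myeloid leukaemia) and state neither strain, sex, time after transplantation nor whether sections come from separate animals. P-values therefore measure spread between these sections. Per the file headers and the values, each matrix deposited by the authors holds raw counts, whole numbers of transcripts per feature and segmented cell, without normalization. The settings behind them (transcript quality threshold, segmentation version, cell filters, decoding software) are not given in the sources used here. The matrices also list 40 negative control probes, 609 negative control codewords, 21 genomic controls, 8096 unassigned codewords and 8 deprecated codewords, which were used only to judge background. Cell positions were not used here, so no distance between cells was measured.

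All deposited cells of a section were summed for the whole-section comparison, and the section was the replicate throughout. The 8 sections held 697983 cells and 105527989 gene transcripts, between 5833895 and 20907439 per section. Values are counts scaled to the usual CPM unit over all gene transcripts of a section, given as mean ± SD over n = 2 control and n = 6 AML sections, and log2 fold changes (AML over control) with their standard error (SE). A CPM is a share of its section, so a large rise of some genes lowers the CPM of the rest; trimmed-mean (TMM) scaling factors lay between 0.920 and 1.14. Averaged per section, a negative control probe was counted between 1.45 and 7.8 times, against 1165 to 4176 times for a gene.

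Cells with at least 30 transcripts (615527 cells) were classified. In an equal subsample of 5000 cells per section, counts were scaled to the cell's total, logged, standardized with values limited to 10, and reduced over 2500 variable genes to 40 principal components. A graph of 20 neighbours was clustered with the Leiden algorithm at resolution 1.0, and every cell took the cluster most frequent among its 15 nearest neighbours in the subsample. Clusters were named from marker lists when at least 3 markers stood 2 times above the other clusters, with at least 1 among the 10 leading genes found in at least 10% of the cluster's cells. A cluster that held markers of different classes, or too few, was called by a pair of its leading genes; the handling of such clusters was settled after the clusters were seen. The class with markers of both blood progenitors and erythroid cells is called the Klf1 Cdkn2a cluster. It met the naming rule above for myeloid progenitors or blasts, with 3 markers raised (Kit, Myb and Myc), 2 of these among its 10 leading genes. It also raised 4 erythroid or megakaryocyte markers. A rule on its high Klf1 and Cdkn2a, settled after the clusters were seen, left it unnamed. The planned class of myeloid progenitors or blasts therefore went to no cluster. Whether the Klf1 Cdkn2a cluster is the leukaemia itself was not tested. No doublet caller was run, because cells were segmented on tissue; transcripts of an adjacent cell can be counted inside an outline, which is why each class was also tested on its own genes. An own gene of a class has a class mean CPM of at least 0.5 times the highest class mean. Class names rest on these markers alone, so that endothelial, for example, stands for endothelial-like. The T cell class also raised 12 markers of natural killer (NK) or innate lymphoid cells, beside 18 T cell markers. Because no cluster was named NK cell, the T cell class may hold NK cells too. With another random subsample, 80.5% of cells kept their class.

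Counts of genes and of cells per class were tested with edgeR quasi-likelihood, AML against control, with TMM scaling for genes, no such scaling for cells, and the filterByExpr filter at a minimum count of 10 for genes. Benjamini-Hochberg adjustment ran over the genes tested or over the 20 classes, with a threshold of 0.05. Class shares were also put to a two-sided exact permutation test on the difference in mean logit share over the 28 splits of 8 sections into groups of 2 and 6. Within 6 classes (endothelial, alveolar type 1, alveolar type 2, fibroblast, alveolar macrophage and T cell) counts were summed per section when it held at least 50 cells of the class. Intervals of single-section shares are 95% Wilson intervals and cover counting error only.

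Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. Of 36 lists fixed for this tissue, 32 had at least 5 tested genes; they cover interferon, TNF and NF-kB, chemokines, interleukins, checkpoints, adhesion, cell cycle, hypoxia, matrix, alveolar and airway epithelium, endothelium, leukocyte and erythroid programmes, complement, p53, protein folding, tissue handling and oxidative stress. The list of sex-linked genes served as a sample check only. Within classes the lists were restricted to own genes, which left 26 list and class pairs. Design, lists, markers, tests and most alternatives were fixed before the data were examined. Genes were named by a rule also fixed then: the 15 largest rises and 10 largest falls with an adjusted p under 0.05 whose AML sections all lay on the same side of both controls, up to 4 members of each called list and 2 of each other list, and within a class up to 6 rises and 6 falls of own genes.

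The file numbers of the sections form 2 runs, controls with AML 1 to 3, and AML 4 to 6. They were treated as possible batches; the later run holds AML sections only. Values for AML 1 to 3 against the controls are therefore given for main genes beside pooled values. Other alternatives were DESeq2 and limma-voom in place of edgeR, upper-quartile scaling, no count filter, the file run as a covariate, a replicate-number block, each section left out in turn, other cell and neighbour minimums, thinned cells, other resolutions and other denominators. Chosen after seeing the data were the sums without the Klf1 Cdkn2a cluster, clustering without the 20 leading genes of that cluster and of the monocyte class, and the separate handling of a shallow endothelial cluster.

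The pipeline was tested on simulated data. Gene counts were drawn, each gene independently, from the mean levels, dispersions and depths of the sections. With 200 genes changed among 4996, the whole-section test recovered 35% of genes changed 2-fold and 75.8% of those changed 4-fold, 3.31% of its calls were false, and it made 0 calls without a change. Within classes between 49.0% and 75.5% of 2-fold and between 80.6% and 100% of 4-fold changes were recovered, with at most 1 call without a change. Of the calls there 3.17% were false in endothelial cells, 5.23% in alveolar macrophages, 5.73% in fibroblasts, 5.75% in alveolar type 2 cells, 5.88% in alveolar type 1 cells and 7.06% in T cells, above the threshold in all but endothelial cells. The list test called the changed list and 0 others, and 1 list when nothing was changed. Correlation between genes, estimated at 0.87 for the G2 and M phase list, was not simulated. False list calls under such correlation were therefore not measured. Shares were simulated at a fixed dispersion rather than that of the sections. There an 8-fold rise and a 3-fold fall were called, with 0 false calls. Recovery of shares at the spread of these sections was not tested. Duplicate sections were checked for and not found: the chi-square per degree of freedom between sections was 34.7 for the controls and 20.4 to 267 for the 15 AML pairs. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, were used.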

Results

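Lung sections of 2 control and 6 AML replicates were compared, so that cell makeup and gene expression of lung in AML could be set against control lung. Control sections held 52060 and 56051 cells with 12962096 and 11226721 gene transcripts. AML sections 1 to 6 held 96693, 64527, 26778, 213040, 80821 and 108013 cells with 19579294, 9874740, 5833895, 20907439, 10593574 and 14550230 gene transcripts. Median transcripts per cell were 214 and 164 in the controls and 169, 126, 187, 73, 103 and 105 in AML 1 to 6, so the AML 4 to 6 sections were the shallowest per cell. Xist, which is expressed from the inactive X chromosome of females, lay between 395 and 783 CPM in the 8 sections.

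The share of each of 20 cell classes was compared first, to ask which cells differ between AML and control lung. The Klf1 Cdkn2a cluster made up 18.2% ± 8.22 of cells in AML sections and 0.0742% ± 0.0092 in controls, a 245-fold rise (log2 7.94 ± 0.91, adjusted p = 0.000628). Its leading genes included Klf1, an erythroid transcription factor, the blood progenitor regulator Myb, the growth regulator Myc and Cdkn2a, which encodes inhibitors of the cell cycle. Control 1 held 34 such cells of 50210, 0.0677% (95% Wilson interval 0.0485 to 0.0946). Control 2 held 43 of 53290, 0.0807% (0.0599 to 0.109). The AML shares ran from 4.59% (4.46 to 4.73) in AML 6 to 30.2% (29.9 to 30.4) in AML 4. Cells of the interstitial macrophage or monocyte class rose from 0.918% ± 0.259 to 8.70% ± 4.12, a 9.47-fold change (log2 3.24 ± 0.63, adjusted p = 0.00984). This class was led by the IgG receptor Fcgr4, the integrin Itgal, the kinase Fgr, and Nr4a1 and Spn, which mark patrolling monocytes. Its AML shares ran from 3.65% (3.50 to 3.80) in AML 2 to 15.6% (15.4 to 15.9) in AML 5.

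None of the 18 other classes passed the test by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. Alveolar type 2 cells, which make surfactant, held 12.4% ± 1.28 of control and 7.60% ± 1.24 of AML cells (log2 −0.71 ± 0.22, adjusted p = 0.0894). Fibroblasts held 12.6% ± 0.42 and 8.20% ± 1.42 (log2 −0.61 ± 0.22, adjusted p = 0.1002). Lymphatic endothelial cells held 0.717% ± 0.0848 and 0.501% ± 0.04698 (log2 −0.52 ± 0.18, adjusted p = 0.1002). Airway ciliated cells held 4.85% ± 1.04 and 1.93% ± 1.35 (log2 −1.33 ± 0.64, adjusted p = 0.241). Endothelial cells held 35.8% ± 1.75 and 30.3% ± 3.72 (log2 −0.24 ± 0.19). Alveolar type 1 cells held 8.31% ± 0.751 and 6.40% ± 1.302, and T cells 2.65% ± 0.623 and 1.96% ± 0.783. Neutrophils held 0.149% ± 0.0514 and 0.193% ± 0.208, and B cells 2.71% ± 1.502 and 2.60% ± 0.441. Clusters left without a class name held 3.40% and 2.22% (Gabrp Cldn10), 0.806% and 0.337% (Adipoq Plin1), 0.258% and 0.671% (Nppa Ttn) and 0.0638% and 0.136% (Cenpf Top2a). Among AML 1 to 3 against the controls, the log2 fold changes were 7.96 for the Klf1 Cdkn2a cluster and 2.97 for the monocyte class, with the same pair of classes called. Shares sum to 100%, so the rise of these classes lowers the others. Over resident cells and lymphocytes alone 0 classes were called by edgeR, 0 with an unadjusted p under 0.05, and alveolar type 2 cells stood at log2 −0.27. Clustered without the 20 leading genes of both classes, an alternative added after seeing the data, the same pair was called, at log2 7.58 ± 0.90 and 3.08 ± 0.62. The exact permutation test of 28 splits gave its smallest possible p of 0.0357 for 5 classes, among them both that rose, and 0.143 after adjustment. Without control 1, and likewise without control 2, 1 class was called, the Klf1 Cdkn2a cluster. With cells thinned to 100 transcripts there were 5, alveolar type 2 cells, fibroblasts and lymphatic endothelium among them as falls.

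**Figure D1:**
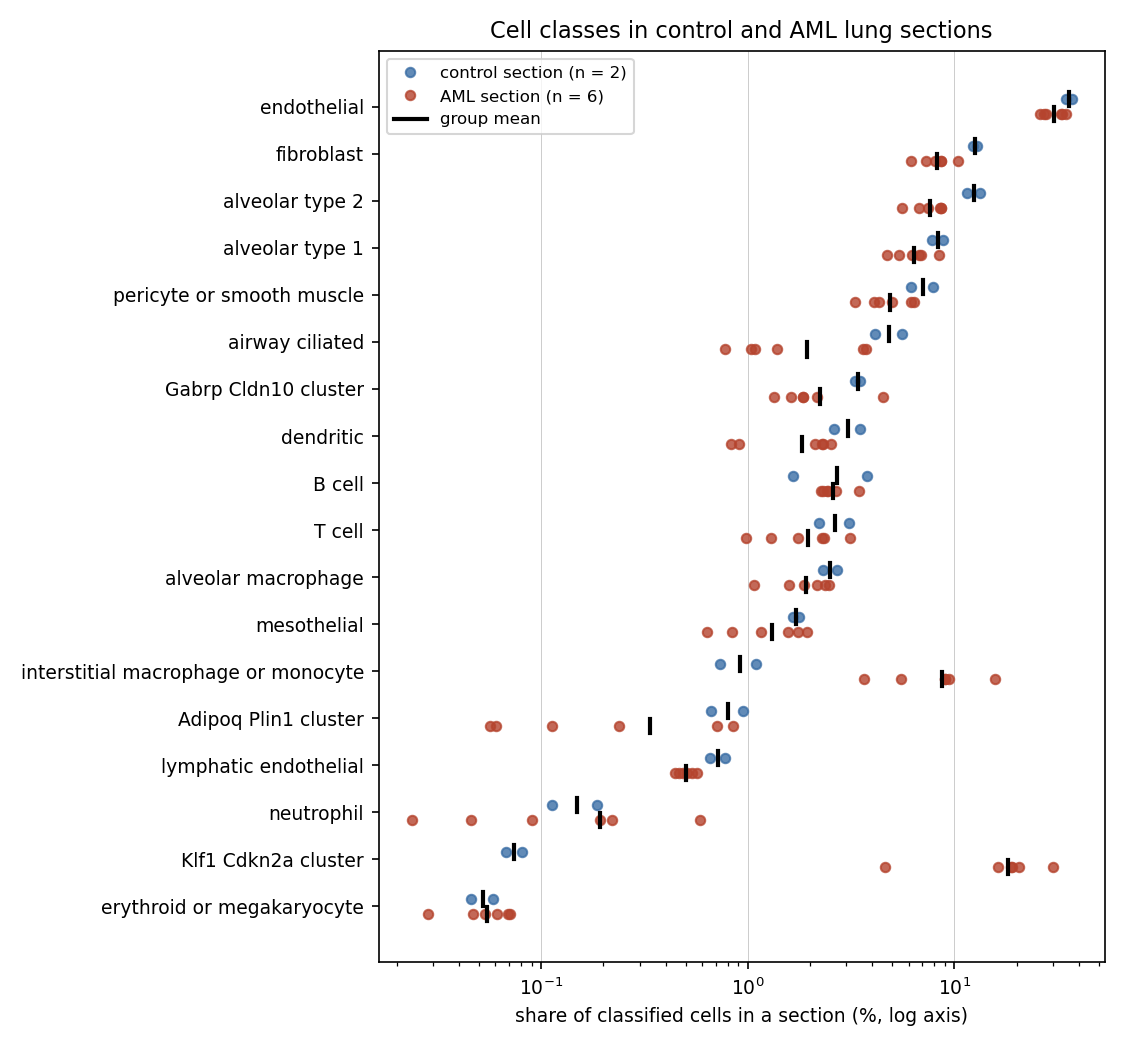
Share of classified cells (%, log axis) for 18 classes, with a point per control (n = 2) and AML section (n = 6) and a bar at each group mean; the Cenpf Top2a and Nppa Ttn clusters are left out. The Klf1 Cdkn2a cluster and the interstitial macrophage or monocyte class lie above both controls in all 6 AML sections, at means of 18.2% and 8.70%.

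Whole sections were compared next, to ask which transcripts differ in the tissue as a whole. Genes of red cell precursors were among the largest rises. Klf1 (ENSMUSG00000054191) went from 7.44 ± 0.70 to 217 ± 78.7 CPM, 29.1-fold (log2 4.86 ± 0.56, adjusted p = 0.00738). Gata1, the erythroid and megakaryocyte transcription factor, went from 4.56 ± 0.23 to 102 ± 46.8 CPM (adjusted p = 0.00814). The red cell pyruvate kinase Pklr rose by 4.94 ± 0.65 on the log2 scale. The membrane skeleton genes Add2 and Ank1 rose by 4.96 ± 1.02 and 4.36 ± 0.62, with the transcription factor Gfi1b at 3.79 ± 0.57. Cdkn2a (ENSMUSG00000044303) rose 27.3-fold, from 23.5 ± 4.14 to 639 ± 274 CPM (adjusted p = 0.00738). Abcb4 (ENSMUSG00000042476), a phospholipid transporter of the bile canaliculus, rose 37.0-fold, from 5.36 ± 0.60 to 197 ± 85.8 CPM (adjusted p = 0.00738). Other large rises were Sfrp4, a secreted Wnt antagonist, at log2 4.31 ± 0.56, Pax6, an eye and brain transcription factor, at 5.15 ± 0.75, the neurofilament gene Nefh at 5.03 ± 0.69 and the developmental regulator Eya4 at 4.38 ± 0.59. Fcgr4 (ENSMUSG00000059089) rose 16.5-fold, from 56.4 ± 8.94 to 906 ± 503 CPM (adjusted p = 0.0098). Cd5l, a protein secreted by macrophages, rose by 4.13 ± 0.78 on the log2 scale (adjusted p = 0.0186).

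Falls were smaller. Hpcal4 (ENSMUSG00000046093), a neuronal calcium sensor, fell from 53.5 ± 8.06 to 8.96 ± 3.50 CPM (log2 −2.60 ± 0.35, adjusted p = 0.00738). Hey1 (ENSMUSG00000040289), a target of Notch signalling, fell from 529.6 ± 30.6 to 185 ± 58.8 CPM (log2 −1.54 ± 0.24, adjusted p = 0.0118). Both were highest in endothelial cells. The endocytic receptor Lrp2 fell from 222 ± 81.1 to 69.3 ± 18.9 CPM (log2 −1.71 ± 0.27, adjusted p = 0.0118). The gelatinase Mmp2 fell from 299 ± 61.5 to 92.0 ± 41.7 (log2 −1.70 ± 0.41, adjusted p = 0.0356), and the circadian transcription factor Dbp from 1655 ± 295 to 549 ± 235 (log2 −1.59 ± 0.39, adjusted p = 0.0384). Also among the 10 largest falls were the lipid transporter Mfsd2a at log2 −1.92 ± 0.48, the anion exchanger Slc26a4 at −1.72 ± 0.38, the mucins Muc5ac at −1.57 ± 0.41 and Muc20 at −1.51 ± 0.29, and the chemokine Cxcl14 at −1.54 ± 0.40, with adjusted p between 0.0186 and 0.0466. In AML 1 to 3 alone, Klf1 stood at log2 4.85, Add2 at 5.61, Fcgr4 at 3.41, Cd5l at 3.08, Hpcal4 at −2.32, Hey1 at −1.43 and Mmp2 at −2.02. In AML 4 to 6, each with no control of its own run, these genes stood at 4.91, 3.76, 4.51, 4.76, −2.93, −1.64 and −1.41.

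Of 4996 genes tested by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 354 passed, 240 higher and 114 lower in AML, against 1234 with an unadjusted p under 0.05. For 353 of the 354 the AML sections lay entirely on the same side of both controls; among all genes 759 did so above and 747 below, 30.1%, where chance gives 7.14%. The Klf1 Cdkn2a cluster was the class of highest expression for 114 of the rises, among 537 tested genes highest there. The dividing Cenpf Top2a cluster was so for 61 of 298, and the monocyte class for 13 of 171. Erythroid or megakaryocyte cells with 15 of 288, neutrophils with 15 of 404 and T cells with 9 of 245 lay near the share over all genes, 240 of 4996. Class means used sections with at least 50 cells of the class. Those of the Klf1 Cdkn2a, Cenpf Top2a and erythroid or megakaryocyte classes came from AML sections only. Rises of genes that lead the Klf1 Cdkn2a cluster are not independent of its larger share. Falls were highest in alveolar type 2 cells for 30 of 141 tested genes and in the epithelial Gabrp Cldn10 cluster for 16 of 258. The fat-gene Adipoq Plin1 cluster had 13 of 293, airway ciliated cells 12 of 422 and endothelial cells 9 of 134. Mesothelial cells had 8 of 303, alveolar type 1 cells 7 of 138 and fibroblasts 5 of 116, against 114 of 4996 over all genes. Summed without the Klf1 Cdkn2a cluster, an alternative added after seeing the data, 0 of 4998 genes passed by edgeR (721 unadjusted), against 255 by DESeq2 and 313 by limma-voom. Without it Fcgr4 stood at log2 4.34, Cd5l at 4.43, Hpcal4 at −2.46 and Hey1 at −1.37, close to their values over all cells, while Klf1 stood at 3.21 and Mki67 at 1.55. The count was 0 without control 1 (603 unadjusted, 266 by DESeq2, 0 by limma-voom) and 0 without control 2 (785 unadjusted, 299 by DESeq2, 90 by limma-voom), 148 without AML 3, 210 without AML 5 and 871 without AML 6. It was 1007 in AML 1 to 3, 155 in AML 4 to 6 and 171 with the file run as a covariate. These shared 354, 86 and 147 genes with the 354, all of which kept their sign in each setting. Because 353 of the 354 had all AML sections on the same side of both controls, a kept sign adds little support.

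**Figure D2:**
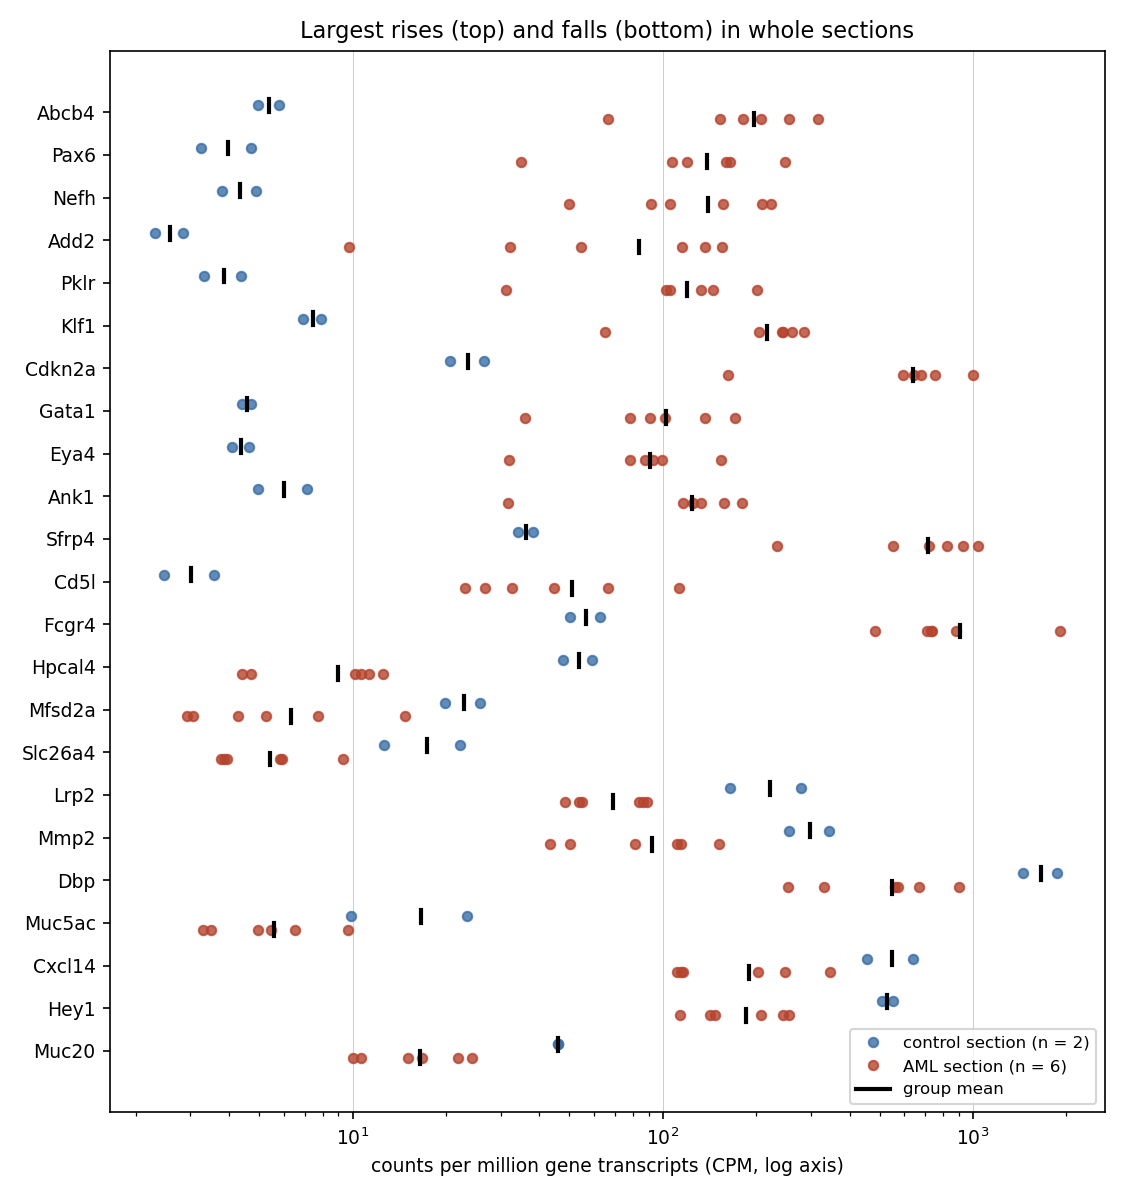
CPM (log axis) of the 13 largest rises (top) and 10 largest falls (bottom) in whole sections, with a point per control (n = 2) and AML section (n = 6) and a bar at each group mean. Klf1 lies between 65.3 and 284 CPM in AML sections, against 7.44 on average in controls, and Hpcal4 between 4.40 and 12.6 CPM against 53.5.

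Fixed gene lists were then compared over whole sections, to ask which programmes moved together. Of 21 G2 and M phase genes 20 rose (20 adjusted over the list alone; list adjusted p = 4.34e-32, and adjusted p = 0.332 with an estimated correlation). Among them were Mki67 at log2 3.13 ± 0.41, Ccna2 at 3.14 ± 0.44, Top2a at 2.87 ± 0.38 and Cenpf at 2.18 ± 0.33. Of 11 S phase genes 10 rose (11 adjusted over the list alone; list adjusted p = 9.68e-15, and adjusted p = 0.392 with an estimated correlation). Uhrf1 stood at 2.80 ± 0.46, Hells at 2.41 ± 0.40 and Dut at 2.23 ± 0.38. Of 7 erythroid and megakaryocyte genes 4 rose (5 adjusted over the list alone; list adjusted p = 6.39e-08, and adjusted p = 0.332 with an estimated correlation). They were Klf1, Gata1, the erythropoietin receptor Epor at 2.46 ± 0.46 and the red cell anion exchanger Slc4a1 at 2.32 ± 0.52. The monocyte and interstitial macrophage list went up (2 of 12 genes rose, 2 adjusted over the list alone; list adjusted p = 0.0162, and adjusted p = 0.906 with an estimated correlation). Spn rose by 2.46 ± 0.27 beside Fcgr4, while Adgre1 stood at 1.15 ± 0.42 and Cx3cr1 at 0.98 ± 0.51 without passing. The p53 and apoptosis list went up (2 of 14 rose, 3 adjusted over the list alone; list adjusted p = 0.0476, and adjusted p = 0.868 with an estimated correlation). Among its members the death-promoting Bid went from 35.7 ± 3.75 to 101.5 ± 22.4 CPM, while Trp53 stood at 0.93 ± 0.29.

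Lists of lung structure went down. Surfactant and alveolar type 2 genes fell in 3 of 5 cases (5 adjusted over the list alone; list adjusted p = 3.19e-05, and adjusted p = 0.422 with an estimated correlation). These were the lamellar body genes Lamp3, from 2789.9 ± 651 to 1301 ± 286 CPM (log2 −1.11 ± 0.25), and Abca3, from 1705 ± 246 to 956 ± 113 CPM (log2 −0.84 ± 0.18), and the mucin Muc1 at −1.10 ± 0.24. Extracellular matrix genes fell in 4 of 20 cases (9 fell and 1 rose adjusted over the list alone; list adjusted p = 0.000171, and adjusted p = 0.868 with an estimated correlation). They were Mmp2, the proteoglycan Vcan at −1.30 ± 0.28, the protease inhibitor Timp1 at −1.18 ± 0.29 and the collagen Col6a1 at −1.15 ± 0.22. Of 10 alveolar type 1 genes 1 fell (3 adjusted over the list alone; list adjusted p = 0.00678, and adjusted p = 0.906 with an estimated correlation). It was the water channel Aqp5, from 1079 ± 149.8 to 540.5 ± 139.7 CPM, while Igfbp2 stood at −1.54 ± 0.43 and Pdpn at −0.93 ± 0.30. Chemokines fell in 2 of 23 cases (2 adjusted over the list alone; list adjusted p = 0.0162, and adjusted p = 0.868 with an estimated correlation), namely Cxcl14 and the lymphatic chemokine Ccl21a at −0.97 ± 0.23. The angiogenesis and capillary lists went down with 0 of 19 and 0 of 14 genes passing by edgeR, over all genes and adjusted over the list alone (list adjusted p = 0.0119 and 0.0355, each with adjusted p = 0.906 with an estimated correlation). Their members Vegfa, the endothelial growth factor, and Plvap, a protein of endothelial openings, stood at −0.94 ± 0.33 and −0.92 ± 0.31, with 6 and 3 genes of these lists at an unadjusted p under 0.05. Cells of the matching classes also held a smaller share of the AML sections, at log2 −0.71 for alveolar type 2 cells and −0.61 for fibroblasts, neither passing by edgeR. The size of these share falls depends on the denominator.

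All 11 gene lists called with the preset correlation were lost with an estimated correlation. Without the Klf1 Cdkn2a cluster, 9 of these gene lists were called, capillary endothelium and angiogenesis being lost. In AML 1 to 3 alone all but the monocyte and p53 lists were called again, and in AML 4 to 6 the cell cycle pair, erythroid, monocyte and surfactant lists.

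Other gene lists did not pass. Of 21 type I interferon genes 19 were higher in AML, with a median of 0.50 and 0 passing by edgeR over all genes or adjusted over the list alone (list adjusted p = 0.0661). Ifi204 stood at 2.11 ± 0.69 (1.36 in AML 1 to 3) and Ifit3 at 0.91 ± 0.44, and 1 gene had an unadjusted p under 0.05. This list was called in AML 4 to 6 and without the Klf1 Cdkn2a cluster. Among 20 hypoxia and glycolysis genes 2 rose, the glucose kinase Hk1 at 1.16 ± 0.23 and the lactate transporter Slc16a3 at 0.94 ± 0.23 (3 adjusted over the list alone; list adjusted p = 0.0588). Of 29 adhesion genes the integrin Itga4 rose, at 1.80 ± 0.27 (1 adjusted over the list alone; list adjusted p = 0.328). Of 33 interleukins and growth factors the alarmin Il33 fell, at −1.11 ± 0.21, and the regulatory cytokine Il10 rose, from 3.18 ± 1.55 to 29.4 ± 23.2 CPM, with log2 3.26 ± 0.85 over all sections and 2.63 in AML 1 to 3 (1 fell adjusted over the list alone; list adjusted p = 0.448, median −0.25, mean 0.03, test downward). Il10 was also the 1 gene of 9 that rose in the regulatory T cell list (1 adjusted over the list alone; list adjusted p = 0.515). Of 28 checkpoint genes Pdcd1lg2, a ligand of PD-1, and Lgals9 rose, at 1.62 ± 0.39 and 1.07 ± 0.28 (3 rose and 1 fell adjusted over the list alone; list adjusted p = 0.692). Myb rose at 2.45 ± 0.48 as the 1 gene of 19 passing in the HOXA and MEIS list (2 rose and 1 fell adjusted over the list alone; list adjusted p = 0.468) and, with Cebpa falling at −0.85 ± 0.17, in the primary granule list of 13 (1 rose and 1 fell adjusted over the list alone; list adjusted p = 0.801).

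Of 13 cytotoxic effectors the protease inhibitor Cst7 rose, at 2.25 ± 0.37 (1 adjusted over the list alone, list adjusted p = 0.731). Of 8 oxidative stress genes the quinone reductase Nqo1 rose, at 1.75 ± 0.44 (1 rose and 1 fell adjusted over the list alone, list adjusted p = 0.803). Of 25 TNF and NF-kB genes the inhibitor Tnfaip3 rose, at 1.75 ± 0.35 (1 adjusted over the list alone, list adjusted p = 0.862, median 0.07, mean −0.02, test upward). By edgeR 0 genes passed, over all genes or adjusted over the list alone, among 8 mature neutrophil genes (list adjusted p = 0.288), 7 of the unfolded protein response (0.413), 17 of endothelial activation (0.578) and 7 of tissue handling (0.663). The same held for 7 alveolar macrophage genes (0.692, median 0.05, mean −0.05, test downward), 17 T cell genes (0.801), 9 B cell genes (0.801), 8 complement genes (0.803) and 16 interferon gamma genes (0.803). In this order, 1, 0, 5, 2, 1, 0, 0, 2 and 1 of these genes had an unadjusted p under 0.05. Of 6 alveolar repair genes 0 passed over all genes, with 1 rising and 1 falling adjusted over the list alone (list adjusted p = 0.888). The B cell list was called upward without control 1 and downward without control 2. Lists of 3 MHC class I genes, 2 MHC class II genes and 3 airway genes were too small to test; of these Muc5ac alone fell, over all genes and adjusted over the list alone.

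Expression within classes was compared to ask which resident cells changed. In endothelial cells (6991 to 55849 per section), 5 of 1199 own genes passed. Hpcal4 fell from 119 ± 13.8 to 18.0 ± 6.62 CPM (log2 −2.81 ± 0.32, adjusted p = 0.0142) and Hey1 from 1201 ± 142 to 423 ± 166 (log2 −1.59 ± 0.29, adjusted p = 0.0406). Smad6, an inhibitor of BMP signalling, fell from 1879 ± 256 to 867 ± 220 (log2 −1.19 ± 0.21, adjusted p = 0.0364), and the growth factor Pdgfb from 1329 ± 319 to 688 ± 96.6 (log2 −1.02 ± 0.18, adjusted p = 0.0364). Bcl3, a co-factor of NF-kB, rose from 37.9 ± 5.89 to 107 ± 24.5 (log2 1.43 ± 0.27, adjusted p = 0.0461). In AML 1 to 3 these genes stood at −2.52, −1.35, −1.26, −0.94 and 1.21. Of the 27 other genes passing, 24 were higher, and 8 and 6 of these were highest in the Klf1 Cdkn2a cluster and the monocyte class. Genes of that cluster were counted in endothelial outlines at a median of 8.68% of its level. The endothelial class also differed in makeup: a cluster with Sox17, Glp1r, Kit, Bmp6 and Hey1 among its leading genes held 22.6% and 21.7% of control cells and at most 15.5% in an AML section. A smaller cluster, with Smad6 and Hey1 among its leading genes, held 1.62% and 1.51%, and at most 1.47% in an AML section. The falls of Hey1 and Smad6 were not tested apart from these shares. Its shallowest cluster held 3.82% and 6.54% of control cells and 5.47 to 22.8% in AML sections. Without that cluster, an alternative added after seeing the data, 47 genes passed, 6 of them own genes. Smad6 kept a smaller fall with a larger error there, log2 −0.95 ± 0.24, and did not pass (adjusted p = 0.0921). In all, 32 of 4710 genes passed (25 higher, 7 lower; 687 unadjusted), 232 in AML 1 to 3 and 4 with the file run as a covariate. Without control 1 or control 2 it was 0 by edgeR (306 and 479 unadjusted; all sections gave 279 by DESeq2 and 257 by limma-voom), and 7, 50, 18 and 209 without AML 3, 4, 5 and 6.

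Alveolar type 1 cells, the thin cells of gas exchange (1393 to 11359 per section), had 22 own genes passing of 930, 4 higher and 18 lower. The water channel Aqp5 fell from 4542 ± 811 to 2562.5 ± 542 CPM (log2 −0.89 ± 0.21, adjusted p = 0.0393), and Hbegf, a ligand of the EGF receptor, from 411 ± 92.0 to 213 ± 24.5 (log2 −1.01 ± 0.15, adjusted p = 0.0119). The collagen Col12a1 fell by 1.42 on the log2 scale, Pdgfb by 1.37, the kinase Prkd1 by 1.03 and the transcription factor Plagl1 by 0.88. Pdgfb was an own gene of endothelial cells too and also fell there. Whether its fall here is one of endothelial transcripts counted in these outlines was not tested. Il6ra, the interleukin 6 receptor chain, rose from 311 ± 103 to 668 ± 130 CPM (log2 1.02 ± 0.22, adjusted p = 0.0294). The receptor Erbb3 rose by 0.87 ± 0.22, the interferon-induced Ifit3 from 287 ± 23.01 to 520.2 ± 92.9 CPM (log2 0.79 ± 0.19, adjusted p = 0.0393) and the TGF-beta mediator Smad3 by 0.63 ± 0.15. In AML 1 to 3 Aqp5 stood at −0.95, Hbegf at −1.09, Il6ra at 1.05 and Ifit3 at 0.70. In AML 4 to 6 these genes stood at −0.85, −0.95, 0.97 and 0.84. Among 127 other rises, 40 and 14 were highest in the Klf1 Cdkn2a cluster and the monocyte class. Genes of that cluster were counted here at a median of 10.6% of its level. In all, 174 of 3581 genes passed (131 higher, 43 lower; 840 unadjusted), 333 in AML 1 to 3 and 3 in AML 4 to 6, with 26 for the file run as a covariate. It was 1 without control 1, 3 without control 2, and 65, 111, 74 and 485 without AML 3, 4, 5 and 6. The number of own genes passing, 22 with all sections, was 45 in AML 1 to 3, 0 by edgeR in AML 4 to 6 and 2 with the file run as a covariate. It was 0 without control 1, 1 without control 2, and 28, 10, 1, 8, 1 and 76 without AML 1 to 6.

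Alveolar type 2 cells (2227 to 9481 per section) had 3 own genes passing of 1145. Lrp2, the endocytic receptor megalin, fell from 986 ± 297 to 463 ± 101 CPM (log2 −1.14 ± 0.20, adjusted p = 0.0221) and the death-promoting Bcl2l11 from 428 ± 51.3 to 309 ± 27.6 (log2 −0.52 ± 0.11, adjusted p = 0.0366), while Spsb2 rose from 174 ± 21.2 to 248 ± 11.4 (log2 0.47 ± 0.11, adjusted p = 0.0444). In AML 1 to 3 they stood at −1.10, −0.50 and 0.46. Of the 83 other rises 21 were highest in the Klf1 Cdkn2a cluster, counted here at a median of 7.51% of its level. Among other falls were the endothelial Hey1 (−1.20 ± 0.23), Pdgfb (−0.90 ± 0.18) and Smad6 (−0.90 ± 0.16), chosen after their values were seen. In all, 100 of 3817 genes passed (84 higher, 16 lower; 722 unadjusted), 157 in AML 1 to 3 and 20 with the file run as a covariate. It was 0 by edgeR without control 1 (281 unadjusted; all sections gave 201 by DESeq2 and 299 by limma-voom), 1 without control 2, and 64, 19, 49, 29 and 249 without AML 2 to 6.

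Fibroblasts (2214 to 10488 cells per section) had 0 of 1205 own genes passing by edgeR, with 6 of 3980 genes passing in all (598 unadjusted; 133 by DESeq2, 65 by limma-voom). These 6, named after their values were seen, were the dividing-cell genes Mki67 (2.61 ± 0.42), Ccna2 (2.63 ± 0.40) and Top2a (2.28 ± 0.35), the blood cell transcription factors Bcl11a (2.41 ± 0.37) and Ikzf1 (1.82 ± 0.25), and Itga4 (1.24 ± 0.20), all higher in AML. Genes of the Klf1 Cdkn2a cluster were counted in fibroblasts at a median of 7.98% of its level. The count was 50 in AML 1 to 3, 0 by edgeR with the file run as a covariate (560 unadjusted), 0 without control 1 (227), control 2 (459), AML 1 (675), AML 3 (575) or AML 5 (529), and 116 without AML 6.

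Alveolar macrophages, the phagocytes of the air space (640 to 2033 per section), had 4 own genes passing of 990, all lower. The neutrophil-attracting chemokine Cxcl2 fell from 57.2 ± 28.7 to 5.89 ± 7.08 CPM (log2 −3.24 ± 0.62, adjusted p = 0.0237), and the transcription factor Egr2 from 581 ± 215 to 211 ± 82.8 (log2 −1.47 ± 0.27, adjusted p = 0.0237). The lipopeptide receptor Tlr2 fell from 2293 ± 413 to 1174 ± 277 (log2 −0.98 ± 0.19, adjusted p = 0.0237) and the myosin Myo1e from 709 ± 101 to 444 ± 70.8 (log2 −0.70 ± 0.16, adjusted p = 0.0459). Cxcl2 rests on few transcripts, 35 and 18 in the controls and 5, 1, 4, 1, 0 and 0 in AML 1 to 6, so the size of its fall is uncertain. In AML 1 to 3 Egr2, Tlr2 and Myo1e stood at −1.58, −0.94 and −0.81. The chemokine Ccl3, not an own gene and named after its value was seen, fell from 435 ± 1.25 to 105 ± 76.2 CPM (adjusted p = 0.0237). All 17 rises were genes of higher level elsewhere, 9 of them in the Klf1 Cdkn2a cluster, counted here at a median of 8.85% of its level. In all, 28 of 3047 genes passed (371 unadjusted), 57 in AML 1 to 3 and 22 with the file run as a covariate. It was 0 by edgeR without control 1 or control 2 (169 and 263 unadjusted; all sections gave 49 by DESeq2 and 84 by limma-voom), and 56, 15, 9 and 68 without AML 1, 3, 5 and 6.

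T cells, here a class that may also hold NK cells (601 to 2936 per section), had 0 of 1132 own genes passing by edgeR. In all, 10 of 2794 genes passed (298 unadjusted, 20 by DESeq2 and 38 by limma-voom). Among them, and named after their values were seen, were Fcgr4 (3.52 ± 0.46), Klf1 (3.62 ± 0.69), Cdkn2a (3.73 ± 0.62) and the semaphorin Sema3f (0.97 ± 0.19) as rises, and as falls the collagens Col6a2 (−1.43 ± 0.27) and Col1a1 (−1.37), the circadian factors Dbp (−1.22 ± 0.23) and Hlf (−1.14 ± 0.22), and Fstl1 (−1.08). Genes of the Klf1 Cdkn2a cluster were counted in T cells at a median of 9.71% of its level. The count was 9 in AML 1 to 3, 29 in AML 4 to 6 and 1 with the file run as a covariate. It was 0 without control 1 (141 unadjusted), 1 without control 2, and 27, 6, 1, 5, 3 and 32 without AML 1 to 6.

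**Figure D3:**
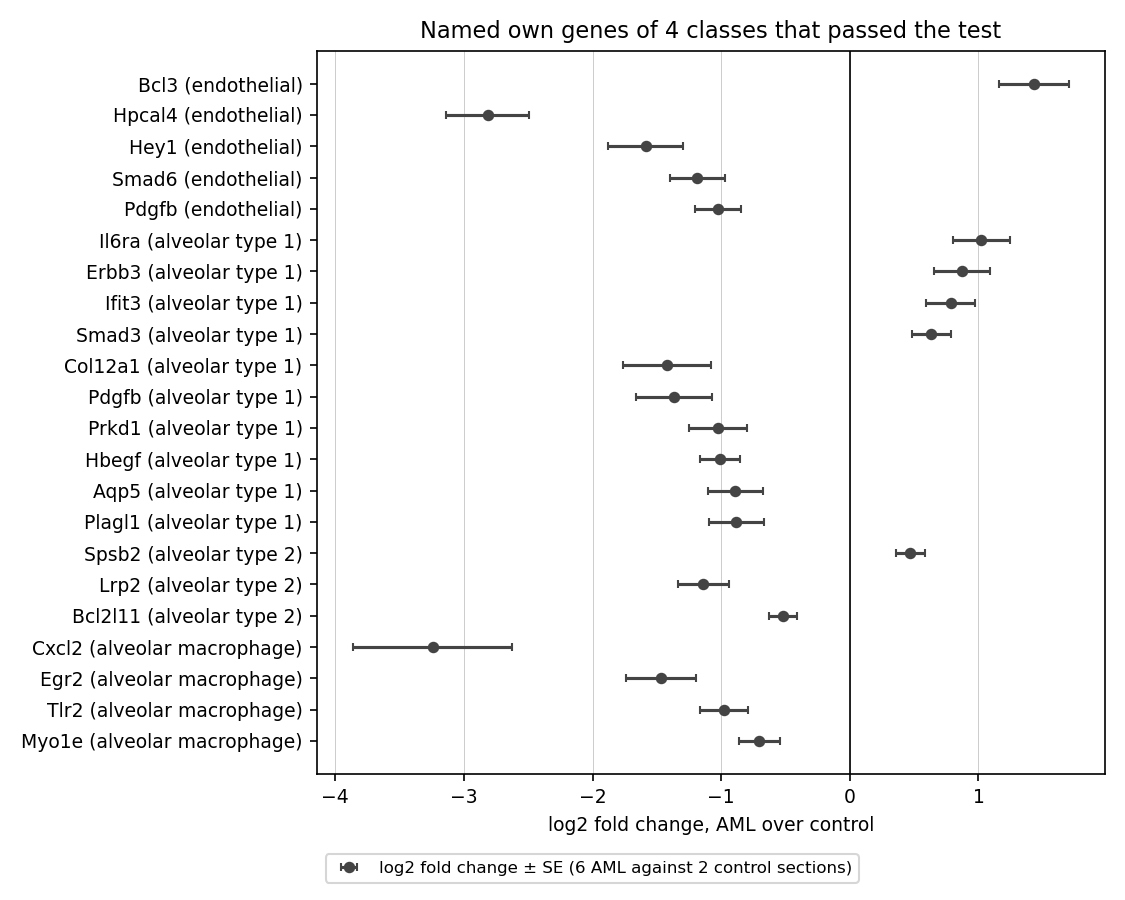
Log2 fold change (AML over control) with its SE of the named own genes that passed the test in endothelial cells, alveolar type 1 cells, alveolar type 2 cells and alveolar macrophages (6 AML against 2 control sections). Cxcl2 in alveolar macrophages lies lowest at −3.24, on few transcripts, and Bcl3 in endothelial cells highest at 1.43.

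**Figure D4:**
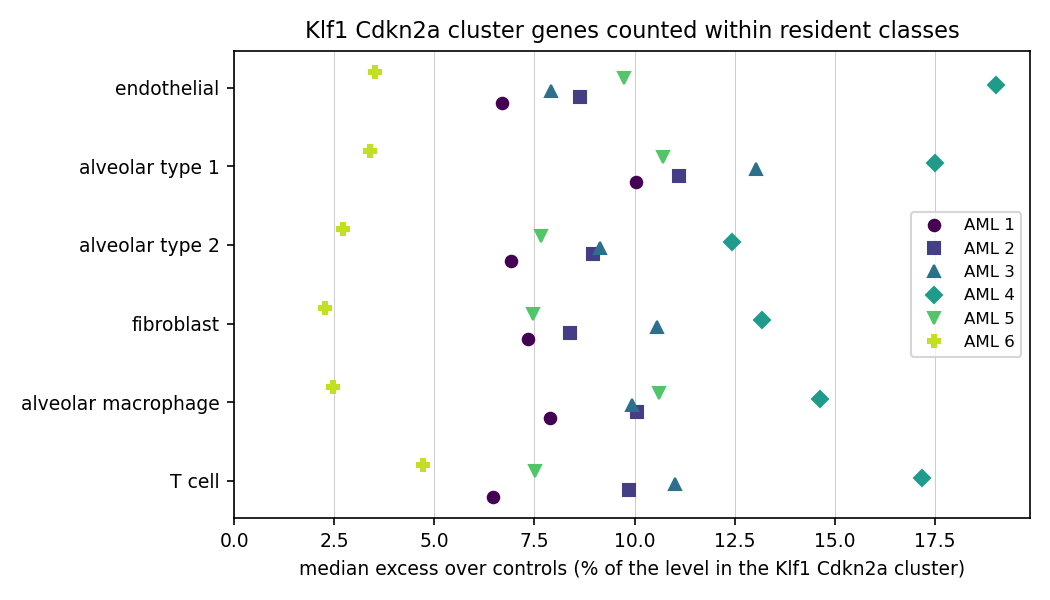
Summed excess over controls of genes of the Klf1 Cdkn2a cluster within 6 resident classes, as a percentage of their summed level in that cluster. Each symbol is an AML section. The axis label names a median, but the values are ratios of sums over genes. AML 4, with 30.2% of its cells in the cluster, lies highest in each class (12.4 to 19.0%), and AML 6, with 4.59%, lowest (2.28 to 4.72%).

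Gene lists restricted to own genes were called in 7 of 26 list and class pairs, each with adjusted p = 0.624 with an estimated correlation. Of 5 surfactant genes in alveolar type 2 cells 0 passed by edgeR over all genes or adjusted over the list alone, with a median of −0.34 (list adjusted p = 0.0237; 3 unadjusted). Lamp3 stood at −0.39 ± 0.17 and Abca3 at −0.34 ± 0.15. Capillary and angiogenesis genes in endothelial cells had medians of −0.43 each over 13 and 11 genes, with 0 passing by edgeR over all genes or adjusted over the list alone (list adjusted p = 0.0237 and 0.0366; 3 and 4 unadjusted). Plvap stood at −0.98 ± 0.32, Aplnr, the apelin receptor, at −1.09 ± 0.39, Nrp1 at −0.57 ± 0.20 and the Notch ligand Dll4 at −0.81 ± 0.36. Plvap, Aplnr and Dll4 are also markers or leading genes of endothelial clusters with smaller shares in AML, and the lists were not tested apart from those shares. Of 10 alveolar type 1 genes in their own class 1 fell, Aqp5 (3 adjusted over the list alone; list adjusted p = 0.0366), with Igfbp2 at −1.46 ± 0.41 and Pdpn at −0.72 ± 0.22. Matrix genes in fibroblasts had a median of −0.49 with 0 of 9 passing by edgeR over all genes (1 rose and 5 fell adjusted over the list alone, 6 unadjusted; list adjusted p = 0.0412). The collagen Col6a1 stood at −0.91 ± 0.23, the matrix protein Tnc at −1.35 ± 0.37 and the collagen cross-linker Lox at 1.63 ± 0.49. The TNF and NF-kB list went up in T cells, median 0.26 over 5 genes with 0 passing by edgeR over all genes (1 adjusted over the list alone; list adjusted p = 0.0366). Tnfaip3, a gene highest in the Klf1 Cdkn2a cluster, stood at 0.95 ± 0.21. The hypoxia list was called upward in alveolar type 2 cells, median 0.20 over 6 genes (list adjusted p = 0.0412). Of these genes 0 passed by edgeR over all genes or adjusted over the list alone, and 0 unadjusted. Pdk1, which holds back pyruvate oxidation, stood at 0.50 ± 0.24, with 0.77 in AML 1 to 3 and 0.18 in AML 4 to 6. Hk2 stood at 0.14 and 0.22 there.

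The 19 other pairs had list adjusted p between 0.162 and 0.876, the smallest for checkpoint genes in T cells (median 0.39 over 10 genes; 0 passing by edgeR over all genes, 2 rose and 1 fell adjusted over the list alone). Cytotoxic genes in T cells had a median of 0.05, a mean of 0.04 and a downward test, endothelial activation genes in endothelial cells a median of −0.08, a mean of 0.20 and an upward test, and p53 genes in T cells a median of −0.05, a mean of 0.01 and an upward test. All 7 called pairs were called again in AML 1 to 3 alone, and 0 pairs in AML 4 to 6 alone or by limma-voom. The number called was 2 without control 1, 4 without control 2, 3 without AML 3 and 0 without AML 1.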

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

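The AML sections were screened for a single section standing apart, which 13 of 175 groups of values showed where about 1 in 20 would by chance. Of the tests named here, the share of cell depth in the alveolar type 1 falls and the share of cell makeup in the clock genes were chosen only after results were seen. AML 1 held 4.52% of its cells in the Gabrp Cldn10 cluster (1.34 to 2.16% in the other AML sections) and 0.587% neutrophils (0.0236 to 0.221%). It also had 31.7 CPM of Cxcl13 (9.52 to 13.7). AML 3 held 3.45% B cells (2.27 to 2.68%). AML 5 had 1899.9 CPM of Fcgr4 (481 to 878), 74.2 CPM of Il10 (7.70 to 29.3) and 52.6 CPM of Pdcd1lg2 (21.1 to 30.7), and it held the largest share of the monocyte class, 15.6%. AML 6, the section with the smallest Klf1 Cdkn2a cluster, had the lowest Klf1, 65.3 CPM (205 to 284). It had the highest values of 4 further genes, Col4a3 at 454 CPM (218 to 268), Ednrb at 225 (119.8 to 157), Nrp1 at 1091 (676 to 820.0) and Thbs1 at 419.7 (188 to 249). In T cells, AML 2 had the lowest Nfkb2, at 71.7 CPM (237 to 319).

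Genes of the Klf1 Cdkn2a cluster were higher within all 6 resident classes of AML sections. If transcripts of these cells are counted inside neighbouring outlines, the excess of a gene should follow its level in the Klf1 Cdkn2a cluster. Over genes chosen as far higher in that cluster than in control cells of the class, the median Spearman correlation was 0.955, which fits that account. Whole cells put in the wrong class would give such a correlation too, so it cannot tell these accounts apart. If whole cells were put in the wrong class, the excess should shrink among cells whose nearest neighbours in expression, not in the tissue, share their class. A median of 0.891 of it was left over the 6 classes, which argues against misplaced cells as its main source. In endothelial cells 0.779 was left, so some misplaced cells stay possible there. Rises of genes such as Klf1 and Cdkn2a within alveolar or T cells may therefore be transcripts of other cells, and hold no evidence of a change in the resident cells. Cell positions were not used, so whether these transcripts come from adjacent cells was not measured.

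Own genes fell in alveolar type 1 cells, 18 with all sections, though 0 own genes passed by edgeR in AML 4 to 6 alone. The 18 genes, chosen with all sections, had a median log2 fold change of −0.87 in AML 1 to 3 and −0.79 in AML 4 to 6. Dilution by transcripts of the Klf1 Cdkn2a cluster would lower every other gene by only 0.16 on the log2 scale (−0.16), against a median of −0.77 for the 18 genes, so it does not account for them. Genes at least 4 times higher in this class than in every other had a median of −0.44 (quartiles −0.60 and 0.10), with 9 of 13 lower. The smallest adjusted p among them by edgeR quasi-likelihood was 0.0639, for Igfbp2. These values leave open whether cells of other resident classes mixed in could add to the falls. Alveolar type 1 cells held a median of 164 transcripts in AML and 266 in control sections. Within the control sections the 18 genes were lower in the shallower cells than in the deeper ones, split at the section's median, by a median log2 ratio of −0.25 (quartiles −0.38 and −0.21). That is less than the falls but not small beside them, so a part played by depth stays open. Median transcripts per cell were also lower in AML than in control sections in the other classes with own genes that fell. They were 86 against 163 in endothelial cells, 147 against 264 in alveolar type 2 cells and 169.5 against 321 in alveolar macrophages. A part of depth in the falls of those classes was not tested.

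Clock genes, named after their values were seen, were shifted: Dbp stood at −1.59 ± 0.39 and Hlf at −0.96 ± 0.23, and Arntl, which peaks in the opposite phase, at 1.59 ± 0.33. A change in cell makeup does not explain this, because Dbp had a median of −1.30 within the 6 classes. In 5 of 6 classes the genes that peak with Dbp were lower and those of the opposite phase higher, the pattern that another hour of tissue collection would give. Collection times are not given in the sources used here, so time of day could not be told apart from an effect of leukaemia.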

How the results depend on the processing

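Chosen only after results were seen were sums without the Klf1 Cdkn2a cluster (in place of the planned class of progenitors or blasts, which no cluster was given), the separate handling of a shallow endothelial cluster, and clustering without 20 leading genes. The cause of the changes below was not tested unless stated. The 354 genes called in whole sections kept their sign in every setting. For 353 of them all AML sections lay on the same side of both controls, so a kept sign adds little support. Genes called within classes kept their sign too. The exception was 1 of 28 in alveolar macrophages, with AML 4 to 6 and with 12 of 15 neighbours in the class. The B cell list, not called with all sections, was called upward without control 1 and downward without control 2.

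For whole sections, 354 genes became 710 with DESeq2, 1102 with limma-voom, 1007 with AML 1 to 3, 155 with AML 4 to 6, 171 with the file run as a covariate, 853 with a replicate block, 0 without the Klf1 Cdkn2a cluster and 0 to 871 with a section left out. Upper-quartile scaling gave 450. With the file run as a covariate the fold changes rest on AML 1 to 3, the AML sections in the run of the controls. Klf1 stood at log2 4.85 both there and in AML 1 to 3 alone. With the replicate block they rest on AML 1 and AML 2, the AML sections whose number a control shares. The replicate block assumes that sections of the same number belong together. The correlation of their residuals was −0.31 for control 1 with AML 1 and 0.38 for control 2 with AML 2. Residuals of 2 controls mirror each other, so the unmatched pairs gave 0.31 and −0.38, and the check does not support the pairing.

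In endothelial cells 32 genes became 279 with DESeq2, 257 with limma-voom, 232 with AML 1 to 3, 117 with AML 4 to 6, 4 with the file run, 399 with the block and 0 to 209 with a section left out. In alveolar type 1 cells 174 became 319, 555, 333, 3 and 26 in the first 5 of these settings, and 1 to 485 with a section left out. In alveolar type 2 cells 100 became 201, 299, 157, 60, 20, 221 with the block, and 0 to 249.

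In fibroblasts 6 genes became 133 with DESeq2, 65 with limma-voom, 50 with AML 1 to 3, 13 with AML 4 to 6, 0 with the file run, 27 with the block, 11 without a count filter, 1 with 12 of 15 neighbours in the class, 0 at resolution 0.5, 0 at resolution 2.0, and 0 to 116 with a section left out. In alveolar macrophages 28 became 49 with DESeq2, 84 with limma-voom, 57 with AML 1 to 3, 43 with AML 4 to 6, 168 with the block, 77 without a count filter and 0 to 68 with a section left out. In T cells 10 became 20 with DESeq2, 38 with limma-voom, 29 with AML 4 to 6, 1 with the file run, 70 with the block, 47 without a count filter and 0 to 32 with a section left out.

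Of the gene lists, 11 became 6 with AML 4 to 6, 0 with an estimated correlation and 9 to 12 with a section left out. Of the within-class gene lists, 7 became 0 with limma-voom, 0 with AML 4 to 6, 0 with an estimated correlation, 62 when all tested genes were used in place of own genes, and 0 to 9 with a section left out. Of the cell class shares, 2 became 0 with the exact permutation test, whose smallest p of 28 splits, 0.0357, became 0.143 after adjustment, 5 with cells thinned to 100 transcripts, 0 over resident cells and lymphocytes, where neither class is counted, 1 with the block and 1 to 3 with a section left out. Clustering without the leading genes gave 2, the same classes.

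Single genes and shares named in the text held or lost their call as follows. With AML 1 to 3, 120 genes were the same, 33 stronger and 2 weaker. With AML 4 to 6, 112 were the same, 2 stronger and 41 weaker. Without control 1, 75 were the same and 80 weaker, and without control 2, 76 and 79. Without the Klf1 Cdkn2a cluster, 49 were the same and 58 weaker.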

Other observations

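The genes of these classes were chosen only after the clusters were seen, and no test was run on them. Values are mean CPM ± SD over 6 AML sections, and levels were compared among 6 classes only. In the Klf1 Cdkn2a cluster, Myb stood at 2601 ± 129, Myc at 1285 ± 168, Klf1 at 766 ± 119, the transferrin receptor Tfrc at 876 ± 74.7, Ank1 at 421 ± 65.3, Cdkn2a at 2106 ± 196 and Trp53 at 1177 ± 167. Each of these was higher than in the endothelial, alveolar macrophage, monocyte, T cell and erythroid or megakaryocyte classes. The erythroid factor Gata1 at 337 ± 62.4 and the erythropoietin receptor Epor at 722 ± 95.4 had higher means in the erythroid or megakaryocyte class, at 755 ± 267 and 838 ± 362. That class held only 12 cells in AML 3 and 103 in AML 4. Its Epor ran from 430 to 1356, across the 634 to 886 of the Klf1 Cdkn2a cluster. Its Klf1 stood at 36.5 ± 41.1 and its Ank1 at 50.8 ± 60.1. Its leading genes included Tubb1, Itga2b and Itgb3, genes of megakaryocytes and platelets, so it is a weak reference for erythroid cells. Kit at 1140.0 ± 153 and Gata2 at 664 ± 120.02 do not set the cluster apart, because endothelial cells held 1239 and 2193. Spi1 at 158 ± 51.0 and Csf1r at 105 ± 28.7 were far below their levels in the monocyte class. Whether the cluster is the leukaemia itself was not tested.

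Cells of the monocyte class in AML sections carried Fcgr4 at 9279.5 ± 1328, Itgal at 3394 ± 732, Csf1r at 2937 ± 512, Spi1 at 2801 ± 371, Nr4a1 at 2179 ± 338 and Cx3cr1 at 615 ± 162, with little Ccr2, at 55.8 ± 21.7. Cd274, the PD-1 ligand, stood at 679 ± 191, below the 975 in alveolar macrophages and above the 75.7 ± 31.4 in the Klf1 Cdkn2a cluster. Whether these monocytes lie close to that cluster was not measured, because cell positions were not used here.

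Of the 21 type I interferon genes tested, Isg15 and Ifi204 were picked after their values were seen. Their spread between AML sections was not tested. Isg15 stood at 466 CPM in AML 5 and 335 in AML 6, against 88.2 to 176 in AML 1 to 4 and 107 and 97.4 in the controls. Ifi204 stood at 147 and 93.0 CPM in AML 5 and AML 6, 25.4 to 59.1 in AML 1 to 4, and 15.7 and 16.3 in the controls. Not every gene of the list had this pattern. Herc6 stood at 252 and 266 CPM in AML 1 and AML 3, against 257 and 250 in AML 5 and AML 6. Ifnar1 stood at 235 and 237 CPM in AML 1 and AML 3, against 182 in AML 5.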
